A study of Mus musculus with 9 samples.

How the data were processed

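The samples were 9 polyadenylated RNA libraries from embryonic day 12 mouse cortex, 3 each from WT, cHet and cKO embryos, and the labels name each as a separate animal. Per the labels' protocols, RNA was extracted with an RNeasy kit and enriched for poly(A) transcripts. Strandedness, read length, aligner and gene annotation are not given in the sources used here. Per the submitters' processing notes, the authors trimmed reads with cutadapt, counted them per gene with featureCounts on mm10 and compared the groups with DESeq2; the notes used here give no versions.

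The values analysed were the authors' deposited tables of 3 comparisons, cHet against WT, cKO against WT and cHet against cKO. Per the file headers, each row holds an Ensembl gene identifier, a gene name, a direction word, a log fold change, its standard error (SE), a statistic and an adjusted p-value. The deposited log fold changes and their SEs were read as log2 values, because the submitters name DESeq2, which reports that base, while the file headers do not state it. The deposited statistic is a score that equalled the log2 fold change divided by its SE in every row. The deposited p-value column held only adjusted values under 0.05, with a highest value of 0.0499, so each table lists genes past that threshold and not the genes that were tested and missed it. Each fold change was read as the first-named group over the second, after the names the authors gave the comparisons. The sign matched the direction word in all 248, 4 and 971 rows of the 3 tables, in the order above. No gene with a known change anchored the sign, so an inversion common to all 3 tables would not be seen.

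The SE in the authors' tables is the error printed beside each fold change, with 3 libraries per group. Counts and values per library were not analysed here, so the depth of each library is unknown and no spread between individual embryos can be given. The planned count-based tests were therefore not run, and the authors' calls were used, as the design had fixed for tables of comparisons.

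Unadjusted p-values were recomputed from the deposited statistics with the normal distribution. The adjusted values then equalled Benjamini-Hochberg values over exactly 15465 genes for cHet against WT, 26976 for cKO against WT and 13375 for cHet against cKO. These numbers were taken as the genes that entered each adjustment by the authors. Identifiers were matched to GENCODE M21, on the same assembly as mm10, and all 248, 4 and 971 identifiers were found. Names follow the tables, or the annotation where a row had none.

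Direction was tested for 39 gene lists of cell types, pathways and gene families, which were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives named below. Where at least 3 members were listed in a table, a two-sided Fisher's exact test compared their split into higher and lower with that of the other listed genes, with Benjamini-Hochberg adjustment over the lists tested in that table. This gave 8 tests for cHet against WT, 16 for cHet against cKO and none for cKO against WT. A one-sided exact hypergeometric test of over-representation was added after seeing the data, for 38 lists per table. It counts every annotated member as tested, so its p-values are upper bounds in that respect. Both list tests take genes as independent. Members that move together are not, and the p-values do not measure differences between embryos. For counts adjusted over the list alone, members outside the table were counted as not passing, so these counts are minimums.

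For genes in both cHet tables, the log2 change of cKO over WT was computed as the difference of the 2 fold changes, with an approximate SE. All implied values assume that the 3 comparisons are unshrunken values of 1 fit. The planned check of this needed genes listed in all 3 comparisons, and there were 0, so it was not run. Chance overlap was simulated 1000 times for unchanged groups that share the cHet libraries, with a correlation of 0.5 between the 2 statistics and genes drawn as independent. Exonic lengths were the merged exons of each gene. Lengths were compared with two-sided permutation tests of 100000 permutations, added after seeing the data. Transcripts of the named genes were aligned to all annotated transcripts with BLAST 2.17.0, keeping matches to other genes of at least 95% identity over 300 bp. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

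The functions were tested on simulated data for 3 groups in which 1 group differed from both others in 200 of 15000 genes. The number of tested genes was recovered exactly. The share of changed genes called was 37.3% at a log2 change of 0.5, 95.5% at 1 and 100% at 2, with 11 false calls. A simulated list with changes of mixed size in 1 direction had an adjusted p of 5.9e-04 in the exact direction test.

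Named genes were the 5 higher and 5 lower with the smallest adjusted p, and the 5 of each direction with the largest fold change. To these came the 4 members with the smallest adjusted p of each list with at least 3 listed members, every gene of a table of at most 10, and Zbtb7a, its 2 relatives and sex-linked genes where listed. For the overlap, the rule took the 5 genes of each direction with the smallest larger adjusted p. Predicted genes without a proper symbol were counted and not named, except in the table of at most 10 genes. The values of some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen, and the text says so. Alternatives were adjusted p thresholds of 0.01 and 0.001, minimum log2 changes of 0.5 and 1, and leaving out predicted genes or blood and sex-linked genes.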

Results

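Gene expression was measured by RNA sequencing in the cortices of 9 mouse embryos at embryonic day 12, when the cortical wall holds dividing radial glia and the first neurons. All embryos carried Cre recombinase at Emx1, a gene active in progenitors of the dorsal telencephalon. They differed in Zbtb7a, which encodes a BTB-domain zinc finger transcription factor. 3 embryos had wild-type Zbtb7a alleles (WT), 3 had 1 floxed allele (conditional heterozygotes, cHet) and 3 were homozygous for it (conditional knockouts, cKO). The series text gives 3 cortices per condition from 2 litters, and the labels do not say which embryo came from which litter. The comparisons ask how expression differs when Cre can delete 1 Zbtb7a allele or both. All fold changes are log2 values of the first-named group over the second with their standard error (SE), from 3 libraries per group, and genes are called listed where the authors' adjusted p was under 0.05.

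The targeted gene was examined first. Zbtb7a lies on chromosome 10 from 81135220 to 81152995 (mm10) and was listed in none of the 3 tables used here, nor were its relatives Zbtb7b and Zbtb7c. The labels do not say which exons are floxed, and a count over a whole gene need not fall when part of it is deleted. The genotype labels are therefore not checked by the expression of Zbtb7a, and levels of Zbtb7a per library were not analysed here.

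Between cKO and WT cortices, 4 genes were listed, 3 lower and 1 higher in cKO. Tdg encodes thymine DNA glycosylase, an enzyme of base excision repair and active DNA demethylation. It was lower by the authors' deposited table, with a log2 fold change of -1.43 (SE 0.19) or a ratio of 0.371, and an adjusted p of 4.7e-09 in the authors' DESeq2 Wald test with Benjamini-Hochberg adjustment. Gjb2, which encodes the gap junction protein connexin 26, had a log2 fold change of -2.27 (SE 0.50) in the authors' deposited table. The predicted protein-coding gene Gm32687 (ENSMUSG00000112640) had a log2 fold change of -7.31 (SE 1.28) in the authors' deposited table, and the processed pseudogene BC002163 one of 2.26 (SE 0.46). In the authors' DESeq2 test the adjusted p was 1.7e-04 for Gm32687, 0.0076 for BC002163 and 0.033 for Gjb2, by the authors' deposited table.

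The 4 genes lie on 3 chromosomes. Tdg spans 82629828 to 82650799 and Gm32687 spans 81863934 to 81881081 on chromosome 10, which places them 1.48 Mb and 0.711 Mb from Zbtb7a. Gjb2 lies on chromosome 14 from 57098600 to 57104702, and BC002163 on chromosome 16 from 42955631 to 42955949. Values of 3 of the 4 genes are uncertain because of near-identical sequence elsewhere. Gm32687 matched Zfp433, also on chromosome 10, at 99.9% identity over 2379 bp. BC002163 matched Ndufs5 on chromosome 4, which encodes a subunit of respiratory complex I, at 99.4% over 319 bp. Tdg matched the processed pseudogenes Tdg-ps at 98.7% over 2968 bp, Gm9855 at 99.2% over 1194 bp and Gm5597 at 99.3% over 1193 bp. Among the 39 gene lists, the list of predicted genes, which holds BC002163 and Gm32687, was the only list with a member in this table. The adjustment covered 26976 genes, and 1 more gene would have needed an absolute statistic of 4.43, which is a log2 change of 0.71 at the median SE of genes listed for cHet against WT.

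**Figure D1:**
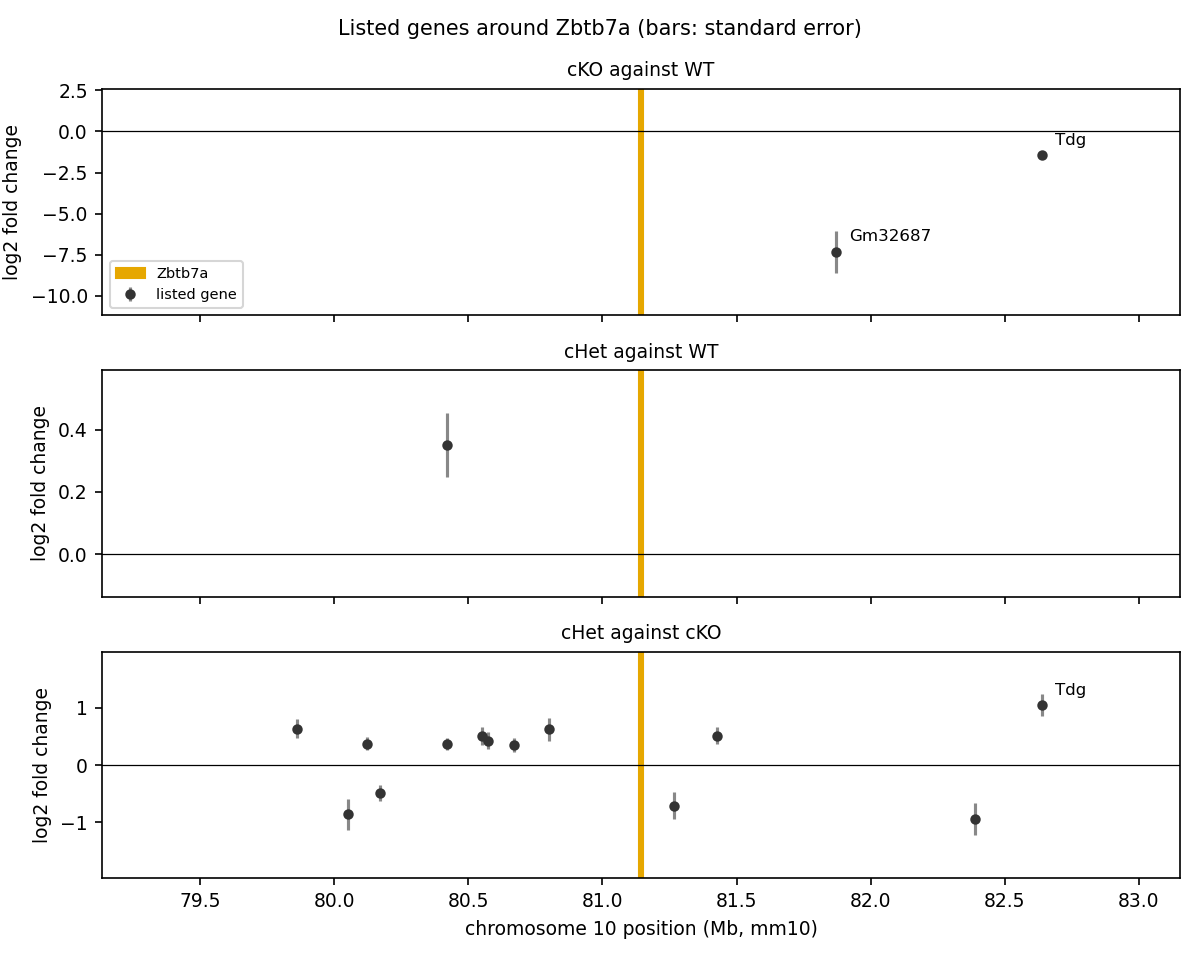
Log2 fold changes of listed genes within 2 Mb of Zbtb7a, by position on chromosome 10 (mm10, Mb), in the authors' deposited tables; vertical bars are the SE and the gold band is Zbtb7a, and the vertical scales differ between panels. Tdg and Gm32687 lie below 0 in cKO against WT, and Tdg lies above 0 in cHet against cKO.

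Between cHet and WT cortices, 248 genes were listed, 126 higher and 122 lower in cHet. Single transcription factor genes were among the higher genes. In the authors' deposited table the log2 fold change was 0.59 (SE 0.11) for Lhx2, 0.65 (SE 0.13) for Fezf2 and 0.56 (SE 0.11) for Mycn. Neuronal genes were among the lower ones. The authors' deposited table gave -0.999 (SE 0.15) for Stmn2, a microtubule regulator of growing axons, and -1.32 (SE 0.19) for the neuronal vesicle protein gene Nsg2. After Eif2s3y, described below, the largest fitted decreases were in genes of the ventral telencephalon, where GABAergic neurons are born. No mean level is given, so whether these sizes come from levels near 0 is unknown. Dlx6 had -7.17 (SE 1.42) and Gsx2 -5.65 (SE 1.51) in the authors' deposited table.

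Increases were smaller than decreases in the median. The median log2 change over listed genes in the authors' deposited table was 0.52 for the higher genes, a ratio of 1.43, and -0.99 for the lower genes, a ratio of 0.504. The highest value was 0.83, for Dusp7, a phosphatase of the ERK pathway, and all 60 genes with an absolute log2 change of at least 1 were lower. Other large increases in the authors' deposited table were Sox3 at 0.82 (SE 0.19), Nfix at 0.78 (SE 0.22), Foxo6 at 0.77 (SE 0.19) and Kat2a at 0.70 (SE 0.16). Rfx4 had 0.67 (SE 0.14) in the authors' deposited table. Among the lower genes with the smallest adjusted p, the authors' deposited table gave -1.37 (SE 0.19) for Sox2ot. In the authors' DESeq2 test the adjusted p, by the authors' deposited table, was 1.2e-04 for Lhx2 and 8.5e-09 for both Sox2ot and Nsg2. Sox2ot spans 34104270 to 34682619 on chromosome 3 and contains Sox2, and Dlx6os1 overlaps Dlx6 on chromosome 6, so reads of these pairs cannot be told apart where strand is unknown.

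Of 24 annotated members of the ventral telencephalon list, 7 were listed in cHet against WT and all 7 fell. Besides Dlx6, the authors' deposited table gave -5.11 (SE 1.26) for Dlx6os1, -5.09 (SE 1.33) for Dlx1 and -4.94 (SE 1.28) for Gad2, which encodes a GABA-synthesising enzyme. The split differed from that of the other listed genes in Fisher's exact test (adjusted p = 0.039 over 8 lists), and the list was over-represented in the added exact hypergeometric test (adjusted p at most 2.6e-06 over 38 lists). Both tests take genes as independent, and the overlapping Dlx6 and Dlx6os1 were counted as separate members. Listed predicted genes also had a differing split, with 11 lower and 2 higher (adjusted p = 0.039, Fisher's exact test). All 14 listed genes that do not code for protein were lower.

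Alongside these ventral genes, the radial glia list had 4 members higher and 1 lower among 20. The authors' deposited table gave 0.54 (SE 0.12) for Emx1 and 0.42 (SE 0.11) for Emx2, both dorsal telencephalic regulators, beside Lhx2 and Sox3. The fifth, Fabp7, was named after its values were seen and had -0.75 (SE 0.20) in the authors' deposited table. The early cortical neuron list had 4 members lower and 1 higher among 20, with -0.66 (SE 0.14) for Gap43 and -0.95 (SE 0.25) for Mapt in the authors' deposited table, and Fezf2 as the higher member. The synapse and axon list had 5 lower of 44, among them Nrxn3 at -2.48 (SE 0.56), Ank2 at -0.46 (SE 0.12) and Slc17a6, a glutamate transporter, at -0.50 (SE 0.14) in the authors' deposited table. The split into higher and lower did not pass for these 3 lists (adjusted p = 0.42, 0.28 and 0.074, Fisher's exact test). All 3 were over-represented in the exact hypergeometric test (adjusted p at most 1.6e-04, 1.6e-04 and 0.0042).

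The list of G1/S genes had 4 of 20 members higher and none lower. They were Mcm3 at 0.63 (SE 0.16), Uhrf1 at 0.64 (SE 0.17), Cdt1 at 0.55 (SE 0.15) and Mcm7 at 0.63 (SE 0.19) in the authors' deposited table. Glycolysis had 5 of 22 members higher and none lower, including Eno1 at 0.67 (SE 0.15), Tpi1 at 0.48 (SE 0.11), Pfkl at 0.49 (SE 0.11) and Pkm at 0.62 (SE 0.16) in the authors' deposited table. Their split missed the threshold (adjusted p = 0.20 and 0.12, Fisher's exact test), and both were over-represented (adjusted p at most 0.0019 and 2.0e-04, exact hypergeometric test). Solute carriers were mixed, with Slc35a4 at 0.56 (SE 0.14), Slc17a6 lower and the cystine transporter gene Slc7a11 at -1.12 (SE 0.31) in the authors' deposited table (adjusted p = 0.62, Fisher's exact test). At an adjusted p under 0.01, 65 genes were left and no list passed the direction test. The ventral list then had 1 member left, too few for a test. With a minimum log2 change of 0.5, no list passed either. Adjusted over the list alone, at least 7 ventral, 5 radial glia, 5 early neuron, 5 synapse, 4 G1/S and 5 glycolysis members passed. These were all the listed members of those lists. They had already passed the adjustment over 15465 genes, so passing this milder one adds no support.

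Eif2s3y, on chromosome Y, had log2 fold changes of -24.80 (SE 3.91) in cHet against WT and -23.04 (SE 3.91) in cHet against cKO in the authors' deposited table. A fitted value of this size gives no readable fold. It was the only listed member among 4 Y-linked genes of the sex-linked list. The sex of the embryos is not given in the labels, so a difference in sex between the groups cannot be told apart from genotype.

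**Figure D2:**
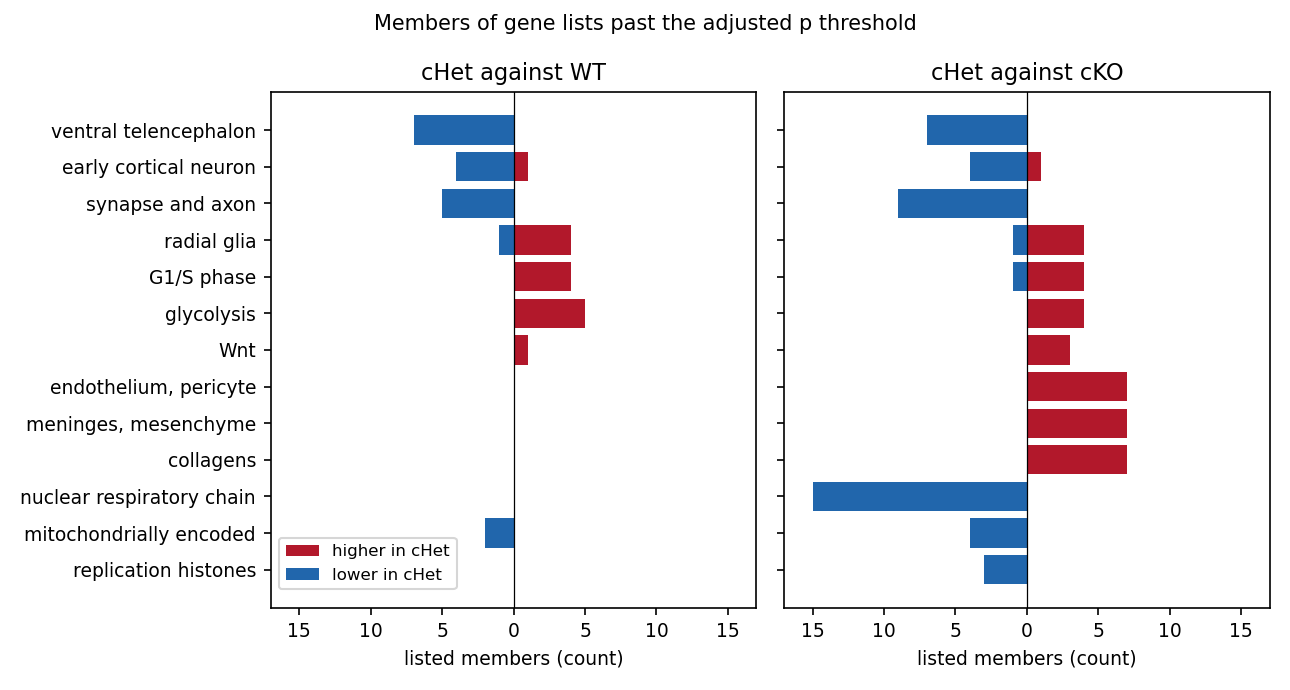
Number of listed members of 13 gene lists in the 2 comparisons of cHet, with members higher in cHet to the right of 0 (red) and members lower in cHet to the left (blue). All 7 listed ventral telencephalon members are lower in each comparison, though they are not all the same genes. In cHet against cKO, 7 endothelium and pericyte members are higher, while 0 are listed in cHet against WT.

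Between cHet and cKO cortices, 971 genes were listed, 417 higher and 554 lower in cHet. Some genes of blood vessels and mesenchyme were higher in cHet. The authors' deposited table gave 1.41 (SE 0.27) for the collagen gene Col15a1, 0.93 (SE 0.24) for Kdr, the VEGF receptor of endothelium, and 0.69 (SE 0.18) for the pericyte receptor gene Pdgfrb. Single neuronal genes were among those lower in cHet. The authors' deposited table gave -1.46 (SE 0.19) for Nsg2, -1.11 (SE 0.15) for Stmn2 and -0.98 (SE 0.15) for Stmn3. Some subunits of the respiratory chain were lower as well, among them Ndufs4 at -1.03 (SE 0.29) in the authors' deposited table.

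Single genes with the smallest adjusted p included Tdg, which was higher in cHet than in cKO by a log2 change of 1.05 (SE 0.19) in the authors' deposited table. Fezf2 had 0.64 (SE 0.13), Kbtbd11 0.57 (SE 0.12) and Lef1, a transcription factor of Wnt signalling, 0.67 (SE 0.14) in the authors' deposited table. Lower in cHet was Sox2ot at -1.35 (SE 0.19) in the authors' deposited table. Besides Col15a1, the largest increases were Cebpb at 1.52 (SE 0.40), Gjb2 at 1.46 (SE 0.50), Enpp3 at 1.32 (SE 0.45) and Fosl2 at 1.26 (SE 0.29) in the authors' deposited table. In the authors' DESeq2 test the adjusted p, by the authors' deposited table, was 5.5e-05 for Tdg, 0.0497 for Gjb2 and 0.0491 for Enpp3. The median log2 change over listed genes in the authors' deposited table was 0.50 for the higher genes and -0.82 for the lower ones.

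The endothelium and pericyte list had 7 of 23 members higher and none lower, with Cdh5 at 1.11 (SE 0.30) and Sox18 at 0.88 (SE 0.25) in the authors' deposited table beside Kdr and Pdgfrb. The meninges and mesenchyme list had 7 of 29 higher, including Col3a1 at 0.97 (SE 0.26), Bgn at 0.72 (SE 0.20), Nid1 at 0.73 (SE 0.22) and Col6a2 at 0.82 (SE 0.26) in the authors' deposited table. Collagens had 7 of 44 higher, with Col4a2 at 1.07 (SE 0.23) and Col4a1 at 0.98 (SE 0.23), both of the vascular basement membrane, in the authors' deposited table. The 3 lists share members, and in each the split of the listed members differed from that of the other listed genes (adjusted p = 0.0084 for each over 16 lists, Fisher's exact test). Over-representation passed for the first 2 lists (adjusted p at most 0.023 and 0.037) and not for collagens (adjusted p at most 0.14, exact hypergeometric test). Of 5 embryonic globin genes and 20 macrophage genes, 1 each was listed, too few for a test, and both were named after their values were seen. The embryonic globin gene Hbb-y had -0.74 (SE 0.24) and the macrophage gene Pf4 had -1.11 (SE 0.29) in the authors' deposited table.

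The synapse and axon list had 9 of 44 members lower and none higher, a split that differed from that of the other listed genes (adjusted p = 0.033, Fisher's exact test). With a minimum log2 change of 0.5, 7 were left lower and the split no longer passed (adjusted p = 0.18, Fisher's exact test). The authors' deposited table gave -2.74 (SE 0.56) for Nrxn3, -1.08 (SE 0.25) for Snap25 and -0.46 (SE 0.12) for Ank2. The ventral telencephalon list had 7 of 24 members lower and none higher, which missed the threshold for direction (adjusted p = 0.0502, Fisher's exact test) and passed for over-representation (adjusted p at most 0.023, exact hypergeometric test). These were not all the same genes as against WT. Dlx6 and Gad1 were listed against WT and not against cKO, and Sp9 and Dlx5 against cKO and not against WT. Gad1, Sp9 and Dlx5 were named after their values were seen. The authors' deposited table gave -5.36 (SE 1.26) for Dlx6os1, -4.49 (SE 1.13) for Dlx2, -5.15 (SE 1.33) for Dlx1, -4.78 (SE 1.28) for Gad2 and -5.55 (SE 1.51) for Gsx2. The radial glia list had 4 higher, with Lhx2 at 0.47 (SE 0.11), Emx1 at 0.42 (SE 0.12) and Emx2 at 0.40 (SE 0.11) in the authors' deposited table, and Fabp7 lower at -1.05 (SE 0.20). The early cortical neuron list had 4 lower, among them Gap43 at -0.73 (SE 0.14) in the authors' deposited table, and Fezf2 higher. Neither split passed (adjusted p = 0.23 and 0.43, Fisher's exact test). Over-representation of these 2 lists, which passed against WT, did not pass here (adjusted p at most 0.067 for each, exact hypergeometric test).

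Of 111 genes of the nuclear respiratory chain, 15 were listed, all lower, a split that differed from that of the other listed genes (adjusted p = 0.0021, Fisher's exact test). Besides Ndufs4, the authors' deposited table gave -0.85 (SE 0.26) for Ndufb3, -0.58 (SE 0.18) for Ndufs8 and -0.95 (SE 0.30) for Uqcrq. Over-representation of this list missed the threshold (adjusted p at most 0.067, exact hypergeometric test). The 4 listed mitochondrially encoded genes were also lower, from -1.19 (SE 0.30) for mt-Nd6 to -1.92 (SE 0.59) for mt-Atp6 in the authors' deposited table, with mt-Nd5 at -1.40 (SE 0.30) and mt-Nd4 at -1.47 (SE 0.48). Replication histones had 3 listed members, all lower, with Hist1h4c at -1.41 (SE 0.39), Hist3h2ba at -0.99 (SE 0.23) and Hist1h2bc at -0.71 (SE 0.24) in the authors' deposited table. The splits of these 2 lists did not pass (adjusted p = 0.22 and 0.33, Fisher's exact test). Neither list was over-represented at the threshold in the exact hypergeometric test. Listed predicted genes had a differing split, with 78 lower and 6 higher (adjusted p = 8.2e-13, Fisher's exact test), and all 50 listed pseudogenes were lower.

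Gene length moved with direction in this comparison. Among listed protein-coding genes, the 482 lower in cHet had a median exonic length of 3060.5 bp and the 416 higher ones 5575.5 bp (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The same comparison for cHet against WT gave 4435.5 and 5015 bp (two-sided permutation p = 0.33). The median over all 22028 annotated protein-coding genes was 3488 bp.

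Other lists in cHet against cKO did not pass the direction test. They did not pass for over-representation either. The adjusted p was at most 0.24 for glycolysis, 0.067 for G1/S and 0.73 for Wnt genes (exact hypergeometric test). Glycolysis had 4 members higher and none lower (adjusted p = 0.067, Fisher's exact test), with Tpi1 at 0.46 (SE 0.11), Eno1 at 0.59 (SE 0.15), Pfkl at 0.43 (SE 0.11) and Pkm at 0.52 (SE 0.16) in the authors' deposited table. The G1/S list had Cdt1 at 0.56 (SE 0.15), Cdc6 at 0.54 (SE 0.16), Uhrf1 at 0.58 (SE 0.17) and Mcm3 at 0.53 (SE 0.16) higher in the authors' deposited table and 1 member lower (adjusted p = 0.23, Fisher's exact test). Wnt genes had 3 members higher, with Fzd7 at 0.47 (SE 0.15) and Tcf7 at 0.64 (SE 0.22) beside Lef1 in the authors' deposited table (adjusted p = 0.14, Fisher's exact test). Zinc finger genes named Zfp were split into 10 higher and 20 lower (adjusted p = 0.40, Fisher's exact test), with Zfp84 at 0.58 (SE 0.15), Zfp553 at 0.54 (SE 0.14), Zfp606 at -0.66 (SE 0.15) and Zfp811 at -0.77 (SE 0.20) in the authors' deposited table. Solute carriers had 2 higher and 3 lower, among them the glutamate transporter gene Slc1a2 at -0.91 (SE 0.23) in the authors' deposited table. At an adjusted p under 0.01, 133 genes were left and no list passed the direction test. The nuclear respiratory chain and the meninges and mesenchyme lists then had 0 members left. The endothelium and pericyte list had 1. These are too few for a test.

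**Figure D3:**
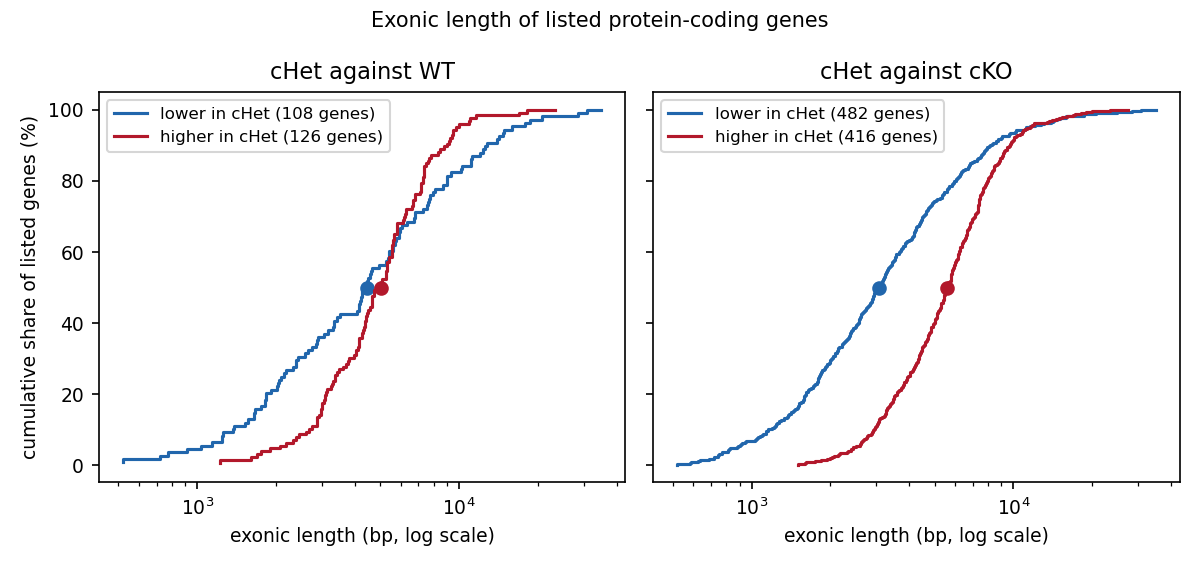
Cumulative share (%) of listed protein-coding genes by exonic length (bp, log axis), for genes lower (blue) and higher (red) in cHet; dots mark the medians. The curves lie apart in cHet against cKO, with medians of 3060.5 and 5575.5 bp.

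The comparisons of cHet against WT and cHet against cKO shared 190 genes, which is 76.6% of the genes listed against WT and 19.6% of those listed against cKO. All 190 had the same direction in both, with 95 higher and 95 lower in cHet. Shared genes with the smallest adjusted p included Fezf2, Mycn, Tpi1, Dmrta2 and Lhx2 on the higher side and Nsg2, Sox2ot and Stmn2 on the lower. Dmrta2, a regulator of cortical progenitors, had 0.51 (SE 0.11) against WT and 0.46 (SE 0.11) against cKO in the authors' deposited table. Mycn had 0.50 (SE 0.11) against cKO in the authors' deposited table.

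Independent lists of these sizes would share 3.93 higher and 5.05 lower genes. Unchanged groups that share the 3 cHet libraries gave a mean of 1.11 shared genes and at most 6 in 1000 simulations, all with the same direction. Genes were drawn as independent there, so differences between libraries that move many genes together are not covered. Values per library were not analysed here, so the shared libraries were not split, and part of the excess may come from sharing them. For the 190 genes, the 2 fold changes imply a median log2 change of cKO over WT of 0.036 (interquartile range -0.034 to 0.098). It was 0.033 for the genes higher in cHet and 0.047 for the lower ones. No implied value differed from 0 by more than its approximate 95% interval, and the slope of one fold change on the other was 1.01 over 189 genes without Eif2s3y. These genes were selected for passing both tests, which share the cHet libraries, so they do not stand for all genes. Implied values near 0 and a slope near 1 arise in part from that selection, and neither was simulated for unchanged groups.

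Of the 4 genes listed for cKO against WT, 3 were also listed for cHet against cKO and none for cHet against WT. In the authors' deposited table BC002163 had -2.89 (SE 0.46) in cHet against cKO. The implied log2 changes of cHet over WT were -0.38 (SE 0.19) for Tdg, -0.81 (SE 0.50) for Gjb2 and -0.64 (SE 0.46) for BC002163, none of which was listed.

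**Figure D4:**
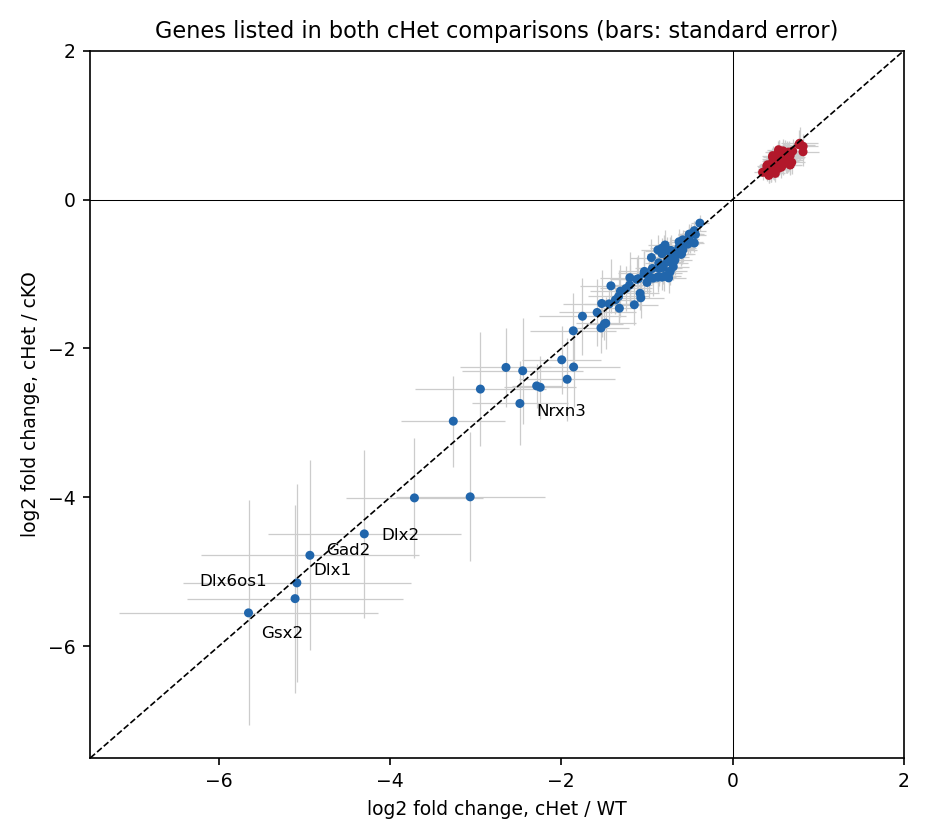
Log2 fold change of cHet over WT (horizontal) and of cHet over cKO (vertical) for 189 of the 190 shared genes, higher (red) or lower (blue) in cHet, in the authors' deposited tables; bars are the SE, the dashed line marks equal values, and Eif2s3y is left out for scale. Genes lie along the line with a slope of 1.01, and Gsx2, Dlx1, Dlx6os1, Gad2 and Dlx2 have the labelled values at the lower left.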

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

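The direction test of the radial glia list and the count of genes called in both cHet comparisons were planned. Their use to weigh the causes below, and the other tests in this part, were chosen only after the results were seen.

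190 genes differed between cHet and WT and also, in the same direction, between cHet and cKO, although cKO embryos lack more Zbtb7a alleles than cHet embryos by their labels. For these 190 genes, a graded effect of Zbtb7a dose, with cKO at or beyond the cHet level, is argued against as the sole cause. It forbids cHet to stand apart from cKO in the direction in which it stands apart from WT. All 190 genes did so and 0 went the opposite way. Genes shared by simulated unchanged groups also all went the same way, so the split alone carries no weight. The number does, with 190 genes against at most 6 in those simulations, which drew genes as independent. This does not exclude a dose effect beside another difference of the cHet libraries. Nor does it cover genes outside the 190, such as Tdg. A difference between litters or stages of the embryos cannot be told apart from genotype, because 0 of 9 libraries have a litter or stage of their own in the labels. The same holds for a difference in sex, which the labels do not give. Of the 190 genes, 4 lie on chromosome X and 1, Eif2s3y, on chromosome Y, and Eif2s3y was lower in cHet in both comparisons. For the ventral telencephalic genes, a smaller share of ventral tissue in the cHet cortices cannot be told apart from a change within cells. The radial glia list had 4 members higher and 1, Fabp7, lower (adjusted p = 0.42, Fisher's exact test), and members that are not listed have no values. That list does not measure the share of ventral tissue, so its direction could not decide this. A response particular to heterozygotes also remains open and was not tested.

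3 genes, Tdg, Gjb2 and BC002163, differed between cKO and WT and also between cHet and cKO. Of the 3 listed protein-coding genes of cKO against WT, 2, Tdg and Gm32687, lie within 2 Mb of Zbtb7a, against 0.021 expected from the 155 of 22028 annotated genes there, expressed or not (exact hypergeometric p = 1.5e-04, one-sided). A strain variant carried along with the floxed allele cannot be told apart from an effect of Zbtb7a dose: for Tdg, the log2 value midway between WT and cKO, where 1 linked allele would put cHet, minus the implied cHet value was -0.16 (SE 0.19), and a graded dose would give the same, while genes within 2 Mb were 1 of 234 listed protein-coding genes in cHet against WT (p = 0.81) and 13 of 898 in cHet against cKO (p = 0.011, exact hypergeometric test, one-sided). Gm32687 was not listed in cHet against cKO, so it has no implied cHet value and the midway check rests on Tdg alone. Reads shared between near-identical copies cannot be told apart from a change of Gm32687, which is 99.9% identical to Zfp433, since no copy was listed in cKO against WT. A change in transcription of these genes that follows from loss of Zbtb7a remains open.

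Genes lower in cHet against cKO were shorter than genes higher in cHet, and pseudogenes, histones and respiratory chain genes were among the lower ones. A transcript length or RNA quality bias between the libraries cannot be told apart from genotype for the shorter genes. In cHet against WT, which shares the cHet libraries, the median log2 length difference was -0.18 (lower minus higher, permutation p = 0.33 over 234 genes), and cKO against WT lists too few genes to show a bias of the cKO libraries. For protein-coding genes listed against cKO and not against WT, median lengths were 2928 bp (lower) and 5780 bp (higher). For those also listed against WT they were 4434 and 5266 bp. A transcript length bias was also examined for the higher vascular, mesenchymal and collagen genes. All 19 listed members were higher, against a mean of 10.6 when directions were shuffled within 5 classes of exonic length. The permutation p was 1e-05, the smallest that 100000 shuffles can give, with genes taken as independent. These vascular, mesenchymal and collagen genes were picked after they had been seen to be all higher, so the test cannot decide this. For these genes a difference in RNA quality, a changed share of vessels or mesenchyme in the cHet or cKO cortices and an effect of Zbtb7a dose on these cells remain open and were not tested.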

How the results depend on the processing

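Alternatives that use the number of genes tested in cKO against WT, protein-coding genes alone, or over-representation were added after seeing the data. In cHet against WT, 248 listed genes became 65 at an adjusted p under 0.01, 28 under 0.001, 60 with a log2 change of at least 1 and 164 when adjusted over 26976 genes. In cHet against cKO, 971 became 133, 43, 166 and 326 in the same order. In cKO against WT, 4 became 2 under 0.001 and 2 without predicted genes. The genes shared by both cHet comparisons, 190, became 52 under 0.01 and 112 when adjusted over 26976 genes, all with the same direction. Except for leaving out predicted genes, which drops Gm32687 and BC002163 by name, each of these settings is stricter by construction. The gene lists past the direction test in cHet against WT, 2, became 0 under 0.01 and 0 with a log2 change of at least 0.5, and 6 passed over-representation; the 6 lists in cHet against cKO became 0 under 0.01. With the log2 minimum in cHet against WT, all 7 ventral genes stayed listed, among 69 higher and 113 lower genes (adjusted p = 0.11, Fisher's exact test). For cHet against cKO, the log2 minimum left 5 of the 6 lists and ended the call of the synapse and axon list. The cause of these losses was not tested.

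The remaining alternatives kept each total within 1.5 times its value, but with a log2 change of at least 0.5 the higher genes fell from 126 to 69 in cHet against WT and from 417 to 214 in cHet against cKO, where the 554 lower genes became 501. In the alternatives run on it, the implied median change of cKO over WT stayed between 0.036 and 0.053. Of 38 named genes in cHet against WT, 20 stayed past 0.01, and of 70 in cHet against cKO, 35 did. Of the 81 named genes, 23 share at least 300 bp at 95% identity or more with another annotated gene, among them Dlx1, Eno1, Pkm, Tpi1, Lef1, Cebpb and the histones, and their values are uncertain to that extent.

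No paired analysis was possible because the tables used here hold comparisons between groups and no value per library. For the same reason leaving out each library in turn, other splits of the samples, other size factors and other count tests were not run, and a minimum mean level was not run because the tables give no mean level. Depth per library is unknown and sets an unknown limit on small changes.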

Other observations

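In cHet against cKO, single members of lists with too few listed genes for a test were listed as follows, named after their values were seen. In the authors' deposited table the NF-kB subunit gene Rela had a log2 fold change of 0.70 (SE 0.19) and the adhesion gene Vcam1 0.47 (SE 0.16). Bhlhe40 of the hypoxia list had 0.72 (SE 0.21) in the authors' deposited table. Rnd2, a gene of intermediate progenitors and migrating neurons, had -0.53 (SE 0.17) in the authors' deposited table. Of the erythroid genes outside the globins, Blvrb had -0.99 (SE 0.27) in the authors' deposited table.

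Barhl2, a homeobox gene on the Cajal-Retzius list, had -1.48 (SE 0.35) against WT and -1.66 (SE 0.35) against cKO in the authors' deposited table, named after its values were seen. Of 15 mitochondrially encoded genes, 2 were listed in cHet against WT, too few for a direction test, with mt-Nd5 at -1.44 (SE 0.30) and mt-Nd6 at -1.24 (SE 0.30) in the authors' deposited table. The X-linked gene Kdm5c, named after its values were seen, had 0.55 (SE 0.16) in cHet against WT in the authors' deposited table. Of the 190 genes shared by both cHet comparisons, 4 lie on chromosome X and 1 on chromosome Y.

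Within 2 Mb of Zbtb7a, 13 of the 898 listed protein-coding genes of cHet against cKO were found, against 6.32 expected (exact hypergeometric p = 0.011, one-sided), and 1 of 234 for cHet against WT, against 1.65 expected (p = 0.81, exact hypergeometric test). These counts, with that for cKO against WT, were the 3 made, after the positions had been seen.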
